A study of Homo sapiens with 8 samples.

How the data were processed

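The series measured transcript levels with a gene expression microarray in U87 cells, an established human glioblastoma line, under 4 conditions. Cells received a control siRNA or an siRNA against RAD18 and were profiled at 72 hours, or expressed a control shRNA or an shRNA against RAD18 and were profiled at day 7. Per the labels' protocols, the control siRNA targeted luciferase, the shRNAs were doxycycline-inducible and delivered by lentivirus, RNA was isolated on columns with DNase treatment, and biotin-labelled cRNA was made from it by the array maker's procedure. The molecule field names polyA RNA, while the extraction text describes total RNA. Each condition has a gene-level record and an exon-level record, 8 records in all. The 5391 probe set numbers that occur in both tables carried identical values in all 4 conditions, so both tables were taken as summaries of the same 4 arrays and each condition was counted as 1 sample. Every record was grouped by its title. The description field of the RAD18 siRNA records names a control siRNA, whereas their titles and source names give RAD18, so the RAD18 signal was examined first as a check of that label.

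The values are log2 signals as deposited by the authors in the series matrix tables. The log2 scale was inferred from the values, which ran from 1.12 to 12.79, were never negative and had nearly equal quartiles in every library. The background correction, normalization, summarization and annotation the authors used are not given in the sources used here, and no scanner files or detection p-values were used. The number of arrays, 1 per condition, limits the precision, and no value has a replicate error. The labels do not mention separate cultures.

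The gene-level table held 53617 probe sets, of which 23866 had 1 gene symbol in the platform annotation, 1852 had several and 27899 had none given. The annotation is old, so symbols were updated to the GRCh38.p14 RefSeq gene table. Of the single-symbol probe sets, 22560 were matched through the gene number, 736 by name and 566 by synonym, and 4 kept their old symbol. Where a symbol had over 1 probe set (661 symbols), the probe set with the highest mean was used. Of the resulting 22354 genes, the 13412 at or above the 40th percentile of mean log2 signal over the 4 libraries (4.19) were kept. The exon-level table held 352859 probe sets, 257971 of them with 1 symbol and 17460 with several. Exon-level probe sets at or above the same percentile (4.5) were kept. No genome build is attached to the tables, so no coordinates are given.

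Each RAD18-targeted library was compared with its own control by the difference of log2 values. With 1 library per group, these differences have no replicate check and no test, and genes were counted by fixed sizes of 1 log2 unit (2-fold) and 0.585 log2 units (1.5-fold). The spread of a contrast is the median absolute deviation of all kept genes scaled to an SD. The control shRNA library was compared with the control siRNA library in the same way as a yardstick. A RAD18 effect common to both experiments was tested over the 4 gene-level libraries with limma 3.58.1 in R 4.3.3, with delivery as a block, 1 residual degree of freedom and Benjamini-Hochberg adjustment over 13412 genes. In that test the only spread is the disagreement between the siRNA and the shRNA experiments. A test of the difference between the 2 contrasts was not made, since it would leave no residual degrees of freedom.

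For 29 gene lists, fixed like every other choice before the data were examined unless stated otherwise, the median difference of the kept members was placed among 10000 random lists of the same size matched on mean signal in 20 bins. A list was said to lie outside the random range when its percentile was below 2.5 or above 97.5. This describes these libraries and is not a test: genes of a list vary together, so random lists of unrelated genes give a range that is too narrow. The mitochondrial DNA-encoded list had under 5 kept members and was not evaluated, which left 28 lists, and 1.4 of them fall outside by construction. Named genes were RAD18, CDKN1A, MKI67, PCNA, UBE2A and UBE2B whatever their values, the 10 genes at each end of each contrast, the 12 genes per direction with the largest smaller difference in both contrasts, 5 genes for each opposite orientation, and up to 4 members of each list outside the random range; uncharacterised loci and small RNAs in these ranks need not be printed. A further gene fixed by name is not reported here.

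On simulated data of 13412 genes for the common effect, limma recovered 8 of 100 genes changed by 1 log2 unit and 93 of 100 changed by 2, with 3 false calls. The simulated changes were equal in both experiments, so these shares do not hold for effects that differ in size between siRNA and shRNA. Both sets of 100 genes were changed at once. The adjustment depends on how many genes change, so the shares do not hold where fewer genes change either. For the siRNA contrast, simulated lists shifted by 0.5, 1 and 2 spreads were recovered in 25.7%, 88.6% and 100.0% of cases, and 5.1% of unshifted lists were called. The shRNA simulation used the same random draws rescaled to its spread, so it gave the same shares by construction. Simulated genes varied independently, so the 5.1% follows from the percentile limits and does not hold for lists whose genes vary together. The alternatives were quantile normalization, median centring, no or a stricter filter (60th percentile), the mean of a gene's probe sets, the median of its exon-level probe sets, other size thresholds, list means, unmatched random lists, no delivery block and a variance trend. The exon-level medians are taken over all probe sets of a gene within each library and then subtracted, so they can set different probe sets against each other. After the data were seen, exchanging the control library, removing a lowess trend on signal (span 0.3) and the median probe set difference were added; the latter subtracts within each kept exon-level probe set and then takes the gene's median. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.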

Results

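Transcript levels were measured on 4 arrays of U87 glioblastoma cells in which RAD18, the E3 ubiquitin ligase that monoubiquitinates PCNA at stalled replication forks, was targeted or not by RNA interference. The series addressed the part RAD18 plays in glioblastoma proliferation. Transient silencing was profiled 72 hours after siRNA transfection and sustained silencing at day 7 of shRNA expression, each beside a control of the same kind, with 1 array per condition. Gene-level log2 signals had medians of 3.91, 3.94, 3.93 and 3.94 in the control siRNA, RAD18 siRNA, control shRNA and RAD18 shRNA libraries, and 13412 genes were compared. All differences below are between single libraries, so they are described by size and the words higher and lower refer to those libraries only.

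RAD18 itself was lower in both targeted libraries. Its gene-level signal (probe set 16950448) was 6.32 in the control siRNA library and 4.81 in the RAD18 siRNA library, a difference of -1.51 log2 units that left 35.0% of the control signal. In the shRNA experiment the signal was 6.86 in the control and 5.98 in the RAD18 shRNA library, a difference of -0.87 that left 54.6%. On the exon level, 11 of the 12 kept RAD18 probe sets were lower with the siRNA and 11 of 12 with the shRNA, with median differences of -1.93 and -1.13. RAD18 was the 96th lowest of all kept genes in the siRNA contrast and the 23rd lowest in the shRNA contrast. The description field that names a control siRNA for the RAD18 siRNA records thus goes against the RAD18 signal, and the titles were kept. Genes of the DNA replication and G1/S list were lower in the RAD18 siRNA library too (median -1.0). A lower RAD18 signal is therefore only a limited check of the label. Between the 2 controls RAD18 differed by 0.53, and against the control siRNA library the RAD18 shRNA library lay only 0.34 log2 units lower (difference -0.34).

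**Figure D1:**
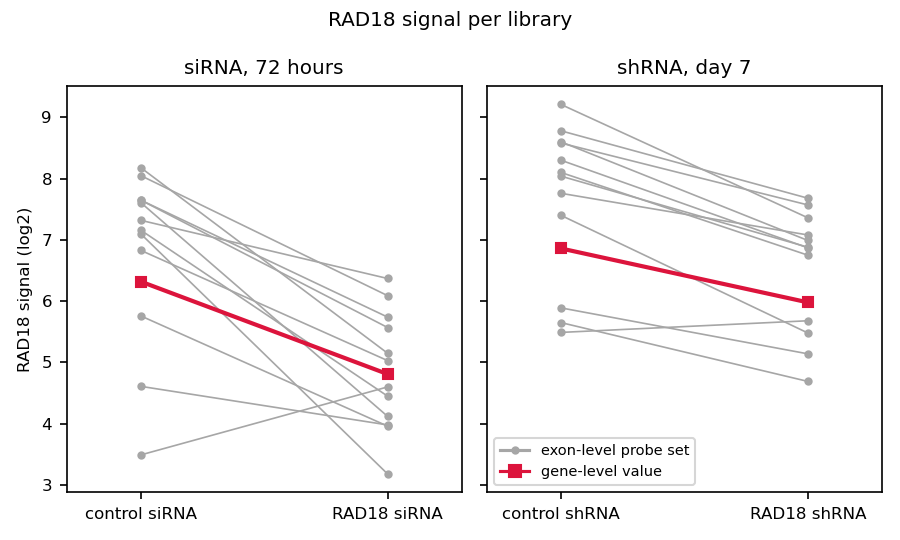
RAD18 signal (log2) in the control and RAD18-targeted libraries for the siRNA at 72 hours (left) and the shRNA at day 7 (right). Grey points joined by lines are the 12 kept exon-level probe sets and red squares the gene-level value, with 1 array per condition; 11 of the 12 lines slope downward in each panel.

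The siRNA comparison asked which transcripts differed after short-term silencing of RAD18. Mitotic genes were the lowest group: all 42 measured members of the G2/M and mitosis list were lower in the RAD18 siRNA library, each by over 1.5-fold and 37 of them by over 2-fold, with a list median of -1.85 log2 units (3.6-fold lower). ANLN, the contractile ring scaffold anillin, was lower by 2.63 log2 units (difference -2.63, 6.18-fold), the mitotic kinesin KIF14 by 5.92-fold, the spindle protein ASPM by 5.65-fold and the condensin subunit NCAPG by 5.55-fold. The proliferation marker MKI67 had a signal of 8.83 in the control and 7.02 in the RAD18 siRNA library, a 3.49-fold difference. The kinetochore genes SKA3 (6.28-fold) and KNL1 (5.42-fold), the mitotic kinase gene PBK (5.65-fold) and DEPDC1 (5.51-fold) were also among the 10 lowest genes, with SKA3 at a median probe set difference (over a gene's kept exon-level probe sets) of -2.32. None of these values has a replicate error.

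Replication and repair genes were lower in the same library. In the DNA replication and G1/S list 42 of 43 members were below the control and 21 were over 2-fold lower, with a median of -1.0. DTL, a substrate adaptor of the CUL4 ubiquitin ligase, was 3.75-fold lower, the ribonucleotide reductase subunit RRM2 3.22-fold, thymidine kinase TK1 3.18-fold and the origin licensing factor CDC6 3.07-fold. The Fanconi anaemia and homologous recombination list had a median of -0.58, with 11 of 22 members over 1.5-fold lower, led by the helicase BRIP1 (4.32-fold), FANCI (3.38-fold), UBE2T (3.14-fold) and BARD1 (2.47-fold). Of 8 measured replication-dependent histone genes 4 were over 1.5-fold lower, among them H1-5 (5.28-fold), H2BC14 (4.32-fold), H1-4 (2.11-fold) and H1-2 (1.97-fold). Among checkpoint genes the median was -0.22, and CLSPN, the claspin adaptor of CHEK1, was 2.52-fold lower, the kinase WEE1 2.47-fold, PRKDC 1.55-fold and H2AX 1.44-fold. The translesion synthesis list lay just below the random range (median -0.17), with 18 of 20 members within 1.5-fold. PCNA was 1.4-fold lower, UBE2V2 1.54-fold and USP1, which deubiquitinates PCNA, 1.47-fold, whereas REV3L, the catalytic subunit of polymerase zeta, was 1.59-fold higher. The E2 partners of RAD18 gave differences of -0.45 for UBE2A and 0.25 for UBE2B, whose kept exon-level probe sets were divided, 3 higher and 2 lower. RRM2 differed by -0.79 with the mean of its probe sets. The translesion list was within the random range without the low-signal filter, with the stricter filter and by its mean, and the checkpoint list by exon-level medians and by median probe set differences.

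Members of the matrix list were among the highest genes in the RAD18 siRNA library. CHI3L1, a secreted glycoprotein and marker of the mesenchymal glioblastoma state, was 12.49-fold higher, the amino acid transporter SLC43A2 10.09-fold and the matricellular protein thrombospondin 1, THBS1, 9.13-fold. KRTAP1-5 (6.73-fold), the lysosomal protease CTSO (5.73-fold), the transmembrane glycoprotein GPNMB (5.03-fold), the CSF1R ligand IL34 (4.76-fold), the transcription factor EHF (4.4-fold), DNAI3 (3.98-fold) and CCN4 (3.87-fold) completed the 10 highest; median probe set differences were smaller for SLC43A2 (2.53 log2 units), IL34 (1.52) and DNAI3 (1.41). The matrix and mesenchymal list had a median of 0.19, with 25 of 32 members above the control and 8 over 1.5-fold higher, among them LUM (3.73-fold) and fibronectin FN1 (2.26-fold). The p53 target list had a median of 0.2 with 26 of 28 members within 1.5-fold; TNFRSF10B (1.7-fold) and TP53INP1 (1.51-fold) passed that size, and the cyclin-dependent kinase inhibitor CDKN1A was 1.48-fold and SPATA18 1.38-fold higher. That list was within the random range by its mean, by exon-level medians and by median probe set differences (0.15). By exon-level medians CDKN1A differed by only 0.13 and TNFRSF10B by 0.15, and SPATA18 by 0.81. Of the kept probe sets 8 of 8 of CDKN1A (median difference 0.6), 9 of 10 of TNFRSF10B (0.78) and 13 of 13 of SPATA18 (0.71) were higher.

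The ribosomal protein, mitochondrial ribosome, hypoxia and glycolysis, integrated stress response and immediate early lists lay below the random range in the siRNA contrast. All 23 measured cytosolic ribosomal protein genes were below the control (median -0.43), 3 of them by over 1.5-fold: RPL27 (1.81-fold), RPS3 (1.69-fold) and RPS19 (1.6-fold); RPL35 was 1.49-fold lower. RPS3 was lower in 8 of its 10 kept probe sets (median difference -0.78); ribosomal protein genes share sequence with many pseudogenes, which limits what single members show. The mitochondrial ribosome list had a median of -0.25, led by MRPL11 (2.04-fold), MRPL9 (1.58-fold), MRPS35 (1.56-fold) and MRPL13 (1.32-fold). The hypoxia and glycolysis list (median -0.33) held PFKFB3 (2.26-fold lower), PGAM1 (2.12-fold lower) and ENO2 (1.8-fold lower), while hexokinase HK2 was 2.32-fold higher. The integrated stress response list (median -0.26) held the serine synthesis genes PSAT1 (5.27-fold lower) and PHGDH (1.65-fold lower), the cystine transporter SLC7A11 (2.0-fold lower) and CEBPG (1.64-fold lower). Immediate early genes had a median of -0.33, within the random range by the list mean, with KLF2 (1.78-fold), CCN1 (1.65-fold) and SRF (1.6-fold) lower and the phosphatase DUSP4 2.49-fold higher. With the control shRNA library in place of the control siRNA library, the integrated stress response (-0.08) and immediate early (-0.12) lists were within the random range and the hypoxia list lay above it (0.5). By median probe set differences MRPL11 differed more (-1.41) and the integrated stress response list was within the random range (-0.16).

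Across all kept genes, 158 were over 2-fold higher and 243 over 2-fold lower in the RAD18 siRNA library, which is 2.99% of 13412. Of the 243 lower genes, 67 belonged to the mitosis, replication, Fanconi and histone lists, which together have 115 kept members. Of 28 lists 13 lay outside the random range, 2 above and 11 below, where 1.4 fall outside by construction. Lists within the range included the senescence secretory (median 0.04), interferon (0.06), NF-kB (0.17), apoptosis (0.05), small RNA silencing (0.11), growth factor receptor (0.11), glioma stem (0.01), cholesterol synthesis (-0.02), oxidative phosphorylation (0.09) and endoplasmic reticulum chaperone (0.11) genes. Markers of astrocytes (0.19), neurons (0.08), oligodendrocytes (-0.21), myeloid cells (0.03) and endothelial or epithelial cells (-0.1) were within it too. Against the control shRNA library the senescence secretory (1.09), NF-kB (1.07), astrocyte (0.46) and interferon (0.27) lists lay above it. The interferon list did so without the low-signal filter (0.13), NF-kB with the stricter filter (0.21), small RNA silencing by exon-level medians (0.34) and neuron markers by the list mean (0.38). Small nucleolar RNAs, a class of short transcripts, had a median of -0.18 over 103 genes, with 24 of them over 1.5-fold lower and 5 higher. Between the 2 controls the class differed more, with a median of 0.41 and 36 genes over 1.5-fold higher in the control shRNA library. The count of 2-fold genes was 958 by exon-level medians, 565 by median probe set differences and 1050 against the control shRNA library.

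**Figure D2:**
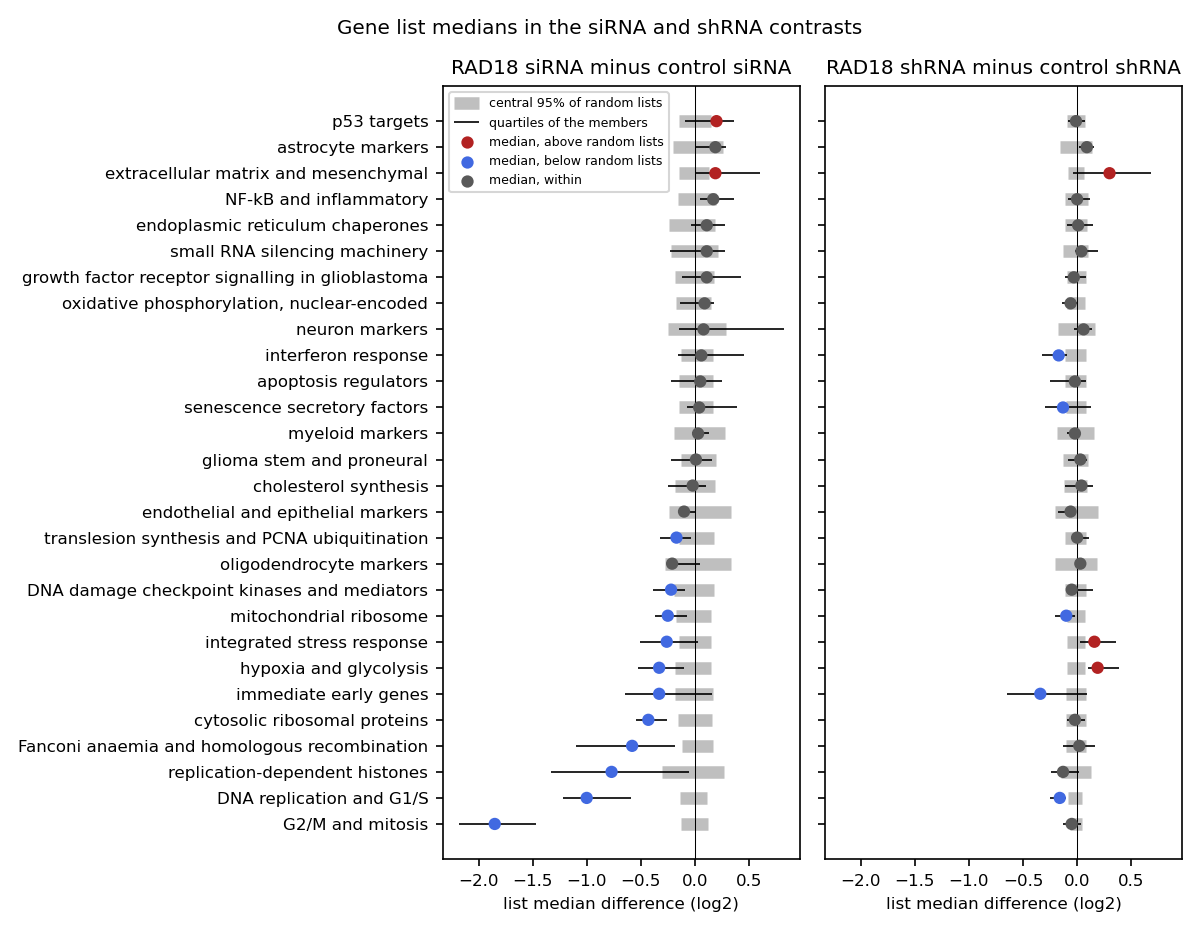
Median log2 difference of each gene list for the siRNA (left) and shRNA (right) contrasts. Grey bars span the central 95% of random lists matched on signal, thin lines the quartiles of the members, and points are coloured by whether the median lies above, below or within the grey bar; the G2/M list is at -1.85 on the left and -0.05 on the right.

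The shRNA comparison asked the same question after sustained silencing. The matrix and mesenchymal list was higher in the RAD18 shRNA library, with a median of 0.3 and 11 of 32 members over 1.5-fold higher. Its leading members were THBS1 (3.75-fold), the collagen cross-linking enzyme LOX (3.33-fold), TGFBI (2.46-fold) and collagen COL1A1 (2.1-fold). Also among the 10 highest genes were tissue factor F3 and carboxypeptidase CPA4 (2.95-fold each), HHIPL2 (2.69-fold), the sarcomeric protein MYPN (2.49-fold), the homeobox gene DLX5 (2.33-fold) and myosin light chain MYL9 (2.29-fold). Immediate early genes were lower, with a median of -0.34 and 6 of 21 members over 1.5-fold lower; FOS was 3.62-fold, FOSB 2.7-fold, and the ERK phosphatases DUSP6 and DUSP4 1.99-fold and 1.85-fold lower. The cytokine IL1B was the lowest gene (5.72-fold), with signals of 5.48 in the control and 2.96 in the RAD18 shRNA library. The latter lies under the filter value of 4.19, which limits what the fold shows. TMEM156 (2.45-fold), DOCK4 (2.03-fold), FCF1 (1.96-fold) and the VEGF receptor KDR (1.96-fold) were also among the 10 lowest genes. FCF1 was lower in 7 of 9 kept probe sets and MYL9 higher in 4 of 4 (median differences -1.26 and 1.23), and FOSB differed by -0.92 with the mean of its gene-level probe sets. Against the control siRNA library the matrix list of the RAD18 shRNA library had a median of -0.03, within the random range.

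Cell-cycle genes lay near the control shRNA library in the RAD18 shRNA library. The G2/M list had a median of -0.05, with all 42 members within 1.5-fold, and MKI67 was 9.59 in the control and 9.53 in the RAD18 shRNA library. The DNA replication and G1/S list lay below the random range at a median of -0.16, with 36 of 43 members below the control; cyclin E1, CCNE1, was 1.87-fold lower, the replication helicase subunit GINS1 1.59-fold, FEN1 1.26-fold and RFC5 1.25-fold. GINS1 was lower in 8 of 8 kept exon-level probe sets (median difference -0.77). The Fanconi (0.02), translesion (0.0), checkpoint (-0.05), histone (-0.13), p53 target (-0.01) and ribosomal protein (-0.02) lists were within the range, the histone list below it with the stricter filter (-0.19) and by median probe set differences (-0.18). Against the control siRNA library the G2/M (0.61), Fanconi (0.5), replication (0.4), checkpoint (0.27) and translesion (0.19) medians lay above the range and the p53 target median (-0.35) below it. PCNA differed by -0.15, CDKN1A by -0.07, UBE2A by 0.26 and UBE2B by -0.29.

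Hypoxia and stress-response genes were higher with the shRNA. The hypoxia and glycolysis list had a median of 0.19 with 24 of 26 members above the control, led by LOX, the prolyl hydroxylase P4HA1 (1.92-fold), PDK1 (1.69-fold) and the glucose transporter SLC2A1 (1.55-fold). The integrated stress response list had a median of 0.16 with 22 of 26 members above, led by STC2 (1.97-fold), VLDLR (1.69-fold), SLC7A11 (1.67-fold) and NUPR1 (1.51-fold). The interferon list lay below the range (median -0.17), with PARP14 (1.48-fold), IFI44 (1.35-fold) and RIGI (1.31-fold) lower and SAMD9L 1.64-fold higher. The senescence secretory list (median -0.13) had 3 members over 1.5-fold higher and 3 lower, among them HGF (1.84-fold lower) and IGFBP7 (1.55-fold higher); CXCL8 had signals of 2.96 in the control and 3.85 in the RAD18 shRNA library, both under the filter value of 4.19. The mitochondrial ribosome list (median -0.1) had no member past 1.5-fold; MRPL15 gave -0.33, MRPS10 -0.31, MRPS31 -0.29 and MRPL16 -0.26. Against the control siRNA library the hypoxia median was -0.62, the senescence secretory median -1.06, and the stress response, interferon and mitochondrial ribosome medians (-0.11, -0.1 and 0.06) were within the range. The senescence list was within it by exon-level medians (-0.09) and by median probe set differences (-0.12), and the mitochondrial ribosome list by exon-level medians (-0.13). By exon-level medians the differences shrank to -0.21 for PARP14, -0.14 for IFI44, -0.03 for RIGI and -0.09 for MRPS10, and grew to -0.91 for MRPS31. Of the kept probe sets 9 of 11 were lower for PARP14, 6 of 7 for IFI44, 11 of 15 for RIGI and 9 of 9 for MRPS10. MRPS31 had a median probe set difference of -0.9.

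Over all kept genes the shRNA contrast had 15 genes over 2-fold higher and 7 over 2-fold lower, 0.16% of 13412, against 401 genes in the siRNA contrast. The spread of the differences was 0.182 log2 units in the shRNA contrast and 0.297 in the siRNA contrast. Of 28 lists 8 lay outside the random range, 3 above and 5 below. The other lists within it were NF-kB (median 0.0 after rounding), apoptosis (-0.02), small RNA silencing (0.04), growth factor receptor (-0.03), glioma stem (0.03), cholesterol synthesis (0.04), oxidative phosphorylation (-0.06) and endoplasmic reticulum chaperones (0.01). Markers of astrocytes (0.09), neurons (0.06), oligodendrocytes (0.03), myeloid cells (-0.02) and endothelial or epithelial cells (-0.06) were within it, and small nucleolar RNAs had a median of 0.06. Against the control siRNA library the NF-kB (-0.83) and chaperone (-0.24) lists lay below the range and the growth factor receptor list (0.22) above it. Astrocyte markers lay above it by exon-level medians (0.24) and by the list mean (0.15), and endothelial or epithelial markers below it by the list mean (-0.25). The count of 2-fold genes was 203 by exon-level medians, 51 by median probe set differences, 36 without the low-signal filter and 293 against the control siRNA library.

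Both experiments together addressed which differences accompany RAD18 targeting whatever the delivery. By the smaller of both differences, the genes leading those higher in both were THBS1, SIPA1L2 (1.85 with the siRNA and 0.93 with the shRNA), the elastic fibre protein MFAP4 (0.91 and 0.89), the proteoglycan LUM (1.9 and 0.87) and CTSO (2.52 and 0.86). Collagen COL1A2 (0.8 and 0.78), DCLK2 (0.75 and 0.82), the imprinted long non-coding RNA MEG3 (0.75 and 0.97), the surface protein CD24 (0.74 and 0.77), the aggrecan-cleaving protease ADAMTS5 (1.4 and 0.74) and BAMBI, a pseudoreceptor for TGF-beta family ligands (0.88 and 0.73), followed. Of these 12 genes, counting 1 small RNA, 3 belong to the matrix list: THBS1, LUM and COL1A2. Lower in both were TMEM156 (-1.88 and -1.29), RAD18, the amino acid transporter SLC6A15 (-0.99 and -0.83), the ribosome biogenesis factor NIP7 (-0.83 and -0.71), GINS1 (-0.94 and -0.67), the transcription factor EGR1 (-0.66 and -0.87) and B4GALT6 (-1.16 and -0.64). Exon-level medians fell under 1.5-fold with the shRNA for SIPA1L2 (0.17), ADAMTS5 (0.28), B4GALT6 (-0.17) and GINS1 (-0.42), and with the siRNA for COL1A2 (0.43). They were larger than the gene-level differences for BAMBI (1.4 and 1.48) and EGR1 (-1.08 and -1.05). Median probe set differences in the shRNA contrast were 0.99 for SIPA1L2 (13 of 16 probe sets higher), 0.65 for ADAMTS5 (9 of 10), -0.54 for B4GALT6 (9 of 10 lower) and 1.74 for LUM. In the siRNA contrast they were 0.8 for COL1A2 (32 of 33 higher), 1.38 for BAMBI and -1.46 for GINS1. MEG3 differed by 0.41 and 0.43 with the mean of its gene-level probe sets. Against the control siRNA library the RAD18 shRNA library was lower for CTSO (5.36 beside 6.39), COL1A2 (8.66 beside 9.19) and ADAMTS5 (5.66 beside 6.51). It was higher for SLC6A15 (7.15 beside 6.89). The other genes named here kept their direction, but LUM (5.9 beside 5.78), NIP7 (6.91 beside 6.95) and GINS1 (5.37 beside 5.42) only narrowly.

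At 1.5-fold in both contrasts, 36 genes were higher in both where 8.36 would be shared by independent lists, and 16 were lower in both against 5.32. In the opposite orientations 18 genes were lower with the siRNA and higher with the shRNA (9.2 for independent lists) and 7 the other way (4.84). The 2 contrasts share no library. Across genes, which are not independent replicates, the log2 differences correlated weakly (Pearson r = 0.062, Spearman rho = 0.06), and 52.0% of genes had the same sign. In the limma test of a common effect no gene passed an adjusted p under 0.05, not even RAD18, the targeted gene. The absence of calls thus does not exclude common effects. Of 13412 genes, 473 had an unadjusted p under 0.05, where 671 are expected by chance. RAD18 had a common difference of -1.19 ± 0.2 (SE; limma, adjusted p = 0.891), TMEM156 -1.59 ± 0.2 and THBS1 2.55 ± 0.34 (SE; limma, adjusted p = 0.891 for both).

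**Figure D3:**
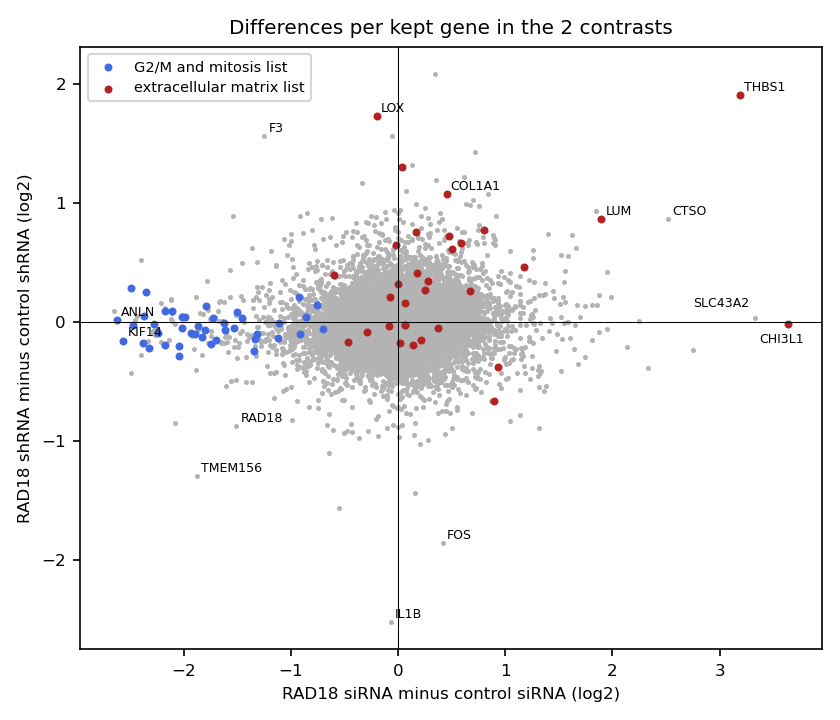
Log2 difference of each of the 13412 kept genes in the siRNA contrast (x axis) and the shRNA contrast (y axis), 1 array per condition. Blue points are the G2/M list, spread along the x axis near 0 on the y axis, and red points the matrix list; THBS1 lies at 3.19 and 1.91.

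The 2 control libraries, which differ in delivery, vector and time, gave a yardstick for differences without RAD18 targeting. They differed by over 2-fold at 270 genes, 98 higher and 172 lower in the control shRNA library, with a spread of 0.286 log2 units, between the spreads of the RAD18 contrasts. The control shRNA library had higher G2/M (median 0.66) and replication genes (0.51) and lower hypoxia (-0.97), senescence secretory (-0.99), NF-kB (-0.84) and matrix genes (-0.45) than the control siRNA library, and 15 of 28 lists lay outside the random range. RAD18 shRNA and control shRNA were the most alike pair of libraries (r = 0.985 across genes), and RAD18 siRNA and control shRNA the least (r = 0.896).

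Exon-level probe sets showed how widely the larger differences were spread over the probe sets of a gene. Among 346 genes past 2-fold in the siRNA contrast with at least 4 kept probe sets, 334 had at least 80% of them on the side of the gene-level difference. All 17 such genes of the shRNA contrast did. The median share over all 10072 genes with at least 4 kept probe sets was 75.0% for the siRNA and 64.3% for the shRNA. THBS1 was higher in 16 of 16 probe sets in both contrasts, CHI3L1 in 11 of 11 with the siRNA, and IL1B was lower in 10 of 10 with the shRNA. Both summaries come from the same arrays and the genes were chosen by their gene-level difference, so a high share was likely beforehand. The shares are therefore no independent check, and they do not cover variation between cultures.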

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

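The hypoxia, integrated stress response and lysosome lists had opposite directions in the siRNA and the shRNA contrast. So had the 10 genes named below, 5 per orientation by the naming rule. At 1.5-fold in both contrasts, 18 genes were lower with the siRNA and higher with the shRNA, and 7 the other way. With 1 library per condition the difference between the contrasts was not tested, for these or for the cell-cycle and matrix lists. The tests on the control library, the proportion to RAD18, the scaling, the culture state, the signal trend, the median probe set differences and the outlying probe sets were chosen after the results were seen.

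The hypoxia and glycolysis list had a median of -0.33 log2 units with the siRNA and 0.19 with the shRNA, and the integrated stress response list -0.26 (-0.16, within the random range, by median probe set differences) and 0.16. A signal-dependent scaling left in the deposited values is argued against: a trend fitted on signal over all genes was at most 0.05 at any member. With it removed the medians were -0.32 and 0.2 for hypoxia and -0.25 and 0.17 for the integrated stress response, still outside the random range. The libraries had nearly equal quartiles as deposited and the random lists were matched on signal, so a small trend was likely beforehand. Scaling of other kinds was not tested. The culture state of single dishes may account for the pattern: the control libraries differed from each other on the hypoxia list by -0.97 (control shRNA minus control siRNA), more than either RAD18 contrast. With 1 dish per condition, culture state and RAD18 targeting cannot be told apart here. An effect of RAD18 that changes with time or delivery also stays open, untested.

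Single genes with opposite differences, siRNA first, were DUSP4 (1.32 and -0.89), ZDHHC12-DT (1.04 and -0.83), GUCY1B1 (1.14 and -0.78), CTSL (0.68 and -0.76) and THBS2 (0.89 and -0.66). In the other orientation they were F3 (-1.25 and 1.56), CXCL8 (-1.54 and 0.89, the latter between signals under the filter value, 2.96 and 3.85), KRT80 (-0.91 and 0.89), MIR129-1 (-0.85 and 0.91) and NBR2 (-0.8 and 0.77, but only -0.18 and 0.17 by the median difference of its 3 kept exon-level probe sets). A lysosome list, chosen after the highest genes of the siRNA contrast were seen, had medians of 0.38 and -0.11.

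Cell-cycle genes were lower in the RAD18 siRNA library and near the control in the RAD18 shRNA library. Set against the control shRNA library, the G2/M median of the RAD18 siRNA library was -2.55, outside the random range of -0.18 to 0.2. That exchange also mixes delivery and time, so it cannot decide whether the control siRNA library was out of place. The control siRNA library was not high beside the other control on this list (control shRNA minus control siRNA, median 0.66). A signal-dependent trend left in the deposited values is argued against. The fitted trend was at most 0.07, and the siRNA median of -1.85 had a 95% bootstrap interval over genes of -2.03 to -1.66. As the quartiles were nearly equal as deposited, a small trend was likely beforehand here too. The same response in proportion to the RAD18 difference would give -1.07 in the shRNA contrast (0.58 times the siRNA median). The median there was -0.05 (95% bootstrap interval over genes -0.1 to 0.01), and 0.61 against the control siRNA library. The bootstrap intervals cover genes that vary together within single libraries and not variation between cultures. The factor of 0.58 has no replicate error, and against the control siRNA library the RAD18 shRNA difference was only -0.34. A threshold in RAD18 level, recovery or selection of cycling cells by day 7, an off-target of the siRNA, and culture density all stay open, and none was tested.

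The matrix list was higher in both contrasts. With each gene at the median of its exon-level probe sets, the list medians were 0.37 with the siRNA and 0.4 with the shRNA. Both lay above the random range (up to 0.16 and 0.08). A few outlying probe sets can hardly move a median over 32 genes, so this outcome was likely beforehand. It comes from the same arrays and is no independent check. A signal-dependent trend left in the deposited values is argued against: the fitted trend was at most 0.05 in size at any member. With it removed the list medians were 0.21 (siRNA) and 0.3 (shRNA), above the random range (up to 0.13 and 0.07). Here too the quartiles were nearly equal as deposited and the random lists matched on signal, so a small trend was likely beforehand. Against the other control the shRNA matrix median was -0.03, so a control shRNA library low in these genes (-0.45 against the control siRNA library) may account for the shRNA part.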

How the results depend on the processing

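The exchange of the control library, the removal of a signal trend and the median probe set difference were chosen after the results were seen. Of 89 alternative values of the main results 70 stayed within the set limits. Quantile normalization, median centring, the stricter filter, the mean of probe sets, list means, unmatched random lists and removal of a signal trend moved none. The limit for counts was a 1.5-fold change, so 565 genes beside 401 with the siRNA counted as unmoved. Quantile normalization and median centring could change little, since the quartiles were nearly equal as deposited. So could the mean of probe sets, since 661 of 22354 symbols had over 1 probe set. The exon-level medians gave larger differences: RAD18 -2.01 (siRNA) and -1.07 (shRNA), 958, 203 and 788 genes past 2-fold for the siRNA, the shRNA and the control comparison, 217 genes shared in direction at 1.5-fold where the gene level gave 52, and a correlation of 0.041. These medians can set different probe sets against each other; subtracting within each kept probe set first, the median probe set difference gave -1.93 and -1.13 for RAD18 and 51 genes past 2-fold with the shRNA. At a threshold of 1.5-fold the 3 comparisons counted 1481, 251 and 1327 genes, and at 1 log2 unit 2 genes were shared, as fewer or more genes pass by construction. Without the low-signal filter the shRNA count was 36, since more genes were compared. With the other control library, an exchange that also mixes delivery and time, RAD18 differed by -2.05 (siRNA) and -0.34 (shRNA) and 1050 and 293 genes passed 2-fold. Among the 21 list medians outside the random range, that exchange turned the sign of 6: hypoxia with the siRNA (0.5), and with the shRNA replication (0.4), integrated stress response (-0.11), hypoxia (-0.62), matrix (-0.03) and mitochondrial ribosome (0.06). It left 12 of the 21 lists outside the random range on the same side and 3 on the other side, against 17 on the same side for exon-level medians and for median probe set differences, 18 for list means, 20 for either filter change and 21 for every other alternative. By exon-level medians RPS3 (0.49, siRNA) and UBE2B (-1.17, siRNA) had the other sign, but not by median probe set difference (-0.78 and 0.08). Of 61 values of named genes that moved by more than 1 spread or changed sign by exon-level medians, 43 stayed within 1 spread by median probe set difference, by which 28 of 163 values moved. The limma test with delivery as a block pairs each RAD18 library with its own control; without the replicate block for delivery it called 0 genes, as did every other alternative, with 95 genes at an unadjusted p under 0.05 (265 to 804 under the others). Leaving out replicates was not possible with 1 library per condition, and leaving out a library from the common-effect fit leaves no residual degrees of freedom. Signal near background limits low genes, and no detection calls were used.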

Other observations

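The gene lists in this part were chosen after the highest and lowest genes had been seen, and the test of the imprinted region after its values were seen, and members are named by their size; each is a hypothesis tested on the same libraries.

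Lysosomal genes were higher with the siRNA. After CTSO, GPNMB and FUCA1 were seen among the higher genes, a list of other lysosomal genes was tested: 33 of its 35 kept members were above the control, with a median of 0.38, at percentile 100 of matched random lists. TPP1 (1.29), NAGLU (1.15), LIPA (1.14) and CTSL (0.68) led, while ARSB (-0.91) and GUSB (-0.44) were lower. This is consistent with lysosomal genes higher as a group with RAD18 siRNA. In the shRNA contrast the same list had a median of -0.11, with 27 of 35 members below the control.

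After FOS, EGR1, DUSP6 and DUSP4 were seen among the lower genes of the shRNA contrast, a list of ERK pathway targets and feedback regulators was tested. Its shRNA median was -0.17, with 19 of 25 members below the control and none past 1.5-fold, at percentile 0.0, which is consistent with ERK pathway output lower with RAD18 shRNA. ETV4 (-0.54), EREG (-0.47), DUSP5 (-0.37) and CCND1 (-0.34) led. The list was also low with the siRNA (median -0.3), where IL11 (-2.02) and HBEGF (-1.78) led and EREG (1.03) was higher. Of its members 10 belong to the lists fixed earlier. Without them the medians were -0.12 (shRNA) and -0.2 (siRNA). These were not placed among random lists, so the percentile holds only for all 25 members.

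TGF-beta and SMAD targets higher in both contrasts was a hypothesis drawn from the matrix genes, BAMBI and ID3. The list median was 0.18 in the shRNA contrast, above the random range. In the siRNA contrast it was 0.02, at percentile 55.92, with 14 of 27 members above the control. The list was thus not higher with the siRNA, although the percentile stayed above the limit set to count against the hypothesis. Between the 2 controls the list differed by a median of -0.15 (control shRNA minus control siRNA), with 22 of 27 members lower. A control shRNA library low in these genes may thus account for the shRNA part. With the shRNA, SMAD6 (0.88), TPM1 (0.82), FBN1 (0.62) and SKIL (0.5) led, and 9 members are also in lists fixed earlier; without them the medians were 0.12 (siRNA) and 0.18 (shRNA).

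MEG3 and SNORD114-28 belong to an imprinted region between DLK1 and MEG9. The 27 other kept transcripts of that region had medians of 0.18 with the siRNA and 0.23 with the shRNA, 22 of 27 above the control in each, and the lower of the 2 percentiles was 99.2. The non-coding RNAs MEG8 (0.55 and 0.51) and MEG9 (0.49 and 0.41) and the small nucleolar RNA SNORD114-17 (0.91 and 0.65) were higher in both, whereas small nucleolar RNAs as a class had medians of -0.18 and 0.06. The controls differed by a median of 0.26 in the same region, and by 0.41 over small nucleolar RNAs as a class (control shRNA minus control siRNA). The region's small RNAs come from near-identical repeated copies, so their probe sets may share signal. The 99.2 percentile may thus overstate how many separate transcripts are higher.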
